A study of Homo sapiens with 6 samples.

How the data were processed

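Poly(A) RNA of MCF-7 cells treated for 24 h with 10 µM karanjin (3 libraries) or 0.1% DMSO vehicle (3 libraries) was sequenced as paired-end reads on an Illumina NovaSeq 6000, per the labels' protocols. Treatment began 48 h after seeding. Libraries were made with a TruSeq RNA kit, with oligo-dT primed reverse transcription and enzymatic removal of the uracil-containing strand, per the labels' protocols. STAR and featureCounts were used with hg38/GRCh38, per the submitters' processing notes. Their versions, the annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Reads of near-identical paralogs and pseudogenes, of overlapping genes and of antisense partners can therefore not be told apart, which leaves the levels of such genes uncertain.

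The authors deposited 1 table of raw counts per Ensembl gene, with whole numbers and no normalization, and each of its 6 sample columns matched 1 sample's labels. Columns of no sample numbered 0. The table holds 58735 genes, the same identifiers as GENCODE release 29 (Ensembl release 94) on GRCh38, from which symbols, coordinates and gene types were taken; 58207 identifiers were also found in a table of gene names used for older symbols. No count was above 0 in any library for 28103 genes. All 37 mitochondrial genes were listed at 0. A check of every pair of libraries by chi-square found no pair of libraries within sampling noise, so all 6 entered as separate samples. Groups and replicate numbers were taken from the labels.

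Counts were tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, robust estimation, R 4.3.3) with TMM scaling and filterByExpr, which kept 15068 genes holding between 99.8% and 99.9% of the counts of each library. The model had an intercept and treatment, p-values were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Every adjusted p given for a gene comes from this test unless another is named. CPM values are TMM-scaled, are given as mean ± SD (n = 3), and folds are fitted values. Standard errors of log2 fold changes were computed from the F statistic. TMM factors lay between 0.947 and 1.02. Principal components used log2 CPM with a prior count of 1.

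Gene lists numbered 31, with 857 symbols of which 855 were found, and covered receptor-driven, stress, cell cycle, metabolic, signalling, lineage and quality-control genes. Each was tested with camera (limma 3.58.1) with the preset correlation of 0.01, adjusted over the 30 lists with tested members, and again with an estimated correlation and with fry. Members were also counted with p-values adjusted over the list alone. Named genes were chosen by rule: the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean CPM of at least 1 and no overlap between groups; in each list up to 3 members with the lowest adjusted p among those called; and a fixed set of AhR, estrogen receptor, stress, cell cycle and survival genes whatever their values. Genes given with their own values outside this rule are said to be chosen after their values were seen; CYP1A2 and list members named without values were named after seeing them too. The groups, the test, the lists, this rule and the first group of settings below were fixed before the data were examined.

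Simulated data with 200 of 15068 genes changed, drawn from the libraries' means and depths with trended dispersions, were tested first for this comparison. A list of 20 further genes was raised 1.5-fold, and these counted as changed in the shares of false calls. The edgeR test called 26.9% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 3.43% of calls false (6.76% with gene-wise dispersions). On the same simulated counts 10.2% of the calls of DESeq2 and 3.40% of those of limma-voom were false. The simulated counts were a single draw per dispersion setting. They lacked the length and GC trends of karanjin replicate 1 and the count pattern of vehicle replicate 1 described below. These shares of false calls therefore need not hold for the real genes and do not rank the tools. Camera called 0 of 99 unchanged lists and called a list of 20 genes raised 1.5-fold (adjusted p = 9.06e-16), whereas the estimated correlation did not (adjusted p = 0.444), nor did fry (adjusted p = 0.164). The simulated genes were drawn independently, whereas estimated correlations within the real lists reached 0.887 (ribosomal proteins). The 0 of 99 therefore cannot tell how often camera falsely calls lists of correlated genes.

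Other settings tried were other scalings (DESeq2 size factors, upper-quartile factors, library totals), other filters (none, or at least 1 CPM in 3 samples), DESeq2 1.42.0, limma-voom, no robust estimation, stricter thresholds, the replicate number as a block, and leaving out each library in turn. Settings chosen after seeing the data halved the counts of vehicle replicate 1, corrected each library for trends with transcript length and GC content (lowess span 0.3, longest annotated transcript, available for 99.96% of tested genes), or left out vehicle replicate 1 and karanjin replicate 1 together. Library totals from 13335058 to 27128751 counts limit low genes: 3 counts in a library equal 0.111 to 0.225 CPM. Intervals for shares of single libraries are Wilson intervals at 95%. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.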

Results

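Messenger RNA was measured by RNA sequencing in MCF-7, an established estrogen receptor-positive luminal breast cancer cell line. Karanjin is a furanoflavonol, a plant flavonoid carrying a fused furan ring. Cells received karanjin at 10 µM (n = 3) or the vehicle, 0.1% dimethyl sulfoxide (DMSO, n = 3), and were collected after 24 h. The files held a whole-number count for each of 58735 Ensembl genes in each of the 6 libraries. The vehicle libraries held 27128751, 13335058 and 16398942 counts for replicates 1, 2 and 3, and the karanjin libraries 14086068, 15526185 and 14986750. A floor of 3 counts in 1 library corresponded to between 0.111 and 0.225 CPM, that is, counts scaled to a common library total. Such floors, like the intervals given below, cover counting error only. The value of 0.111 belongs to vehicle replicate 1, in which both reads of a pair may have been counted singly, as described under other observations. If so, its floor is too low and its interval too narrow. KRT8, a luminal keratin, took the largest number of counts in each library. The 37 genes of the mitochondrial chromosome, 13 of them mRNAs, were listed at 0 in all 6 libraries, so no list of mitochondrially encoded genes was tested.

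The single comparison in the design asks which transcripts differ after 24 h of karanjin in MCF-7 cells. CYP1A1, a cytochrome P450 that is the classical target of the aryl hydrocarbon receptor (AhR), rose most among all tested genes, from 25.3 ± 4.50 to 1805 ± 153 CPM (SD, n = 3 each), a 71.8-fold increase. SLC7A5, the light chain of the large neutral amino acid transporter LAT1, rose 7.93-fold, and CYP1B1, a second AhR-responsive cytochrome P450, rose 6.01-fold. ESR1, which encodes estrogen receptor alpha, fell from 301 ± 26.5 to 163 ± 19.6 CPM, 1.85-fold lower. Of 15068 genes tested, 105 were higher and 91 lower with karanjin.

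Among the genes that passed, 95 of the 105 higher and 82 of the 91 lower were protein coding. A change of at least 2-fold was found for 56 higher and 29 lower genes. At least 4-fold changes numbered 11 higher and 1 lower. That 1 lower gene, the clone-named AC127070.4, lay below the expression minimum for named genes and was picked out after its values were seen. The 3 karanjin values lay wholly outside the range of the 3 vehicle values for all 196 genes that passed. The same held for 3347 of all tested genes (22.2%), where chance gives 10%.

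**Figure D1:**
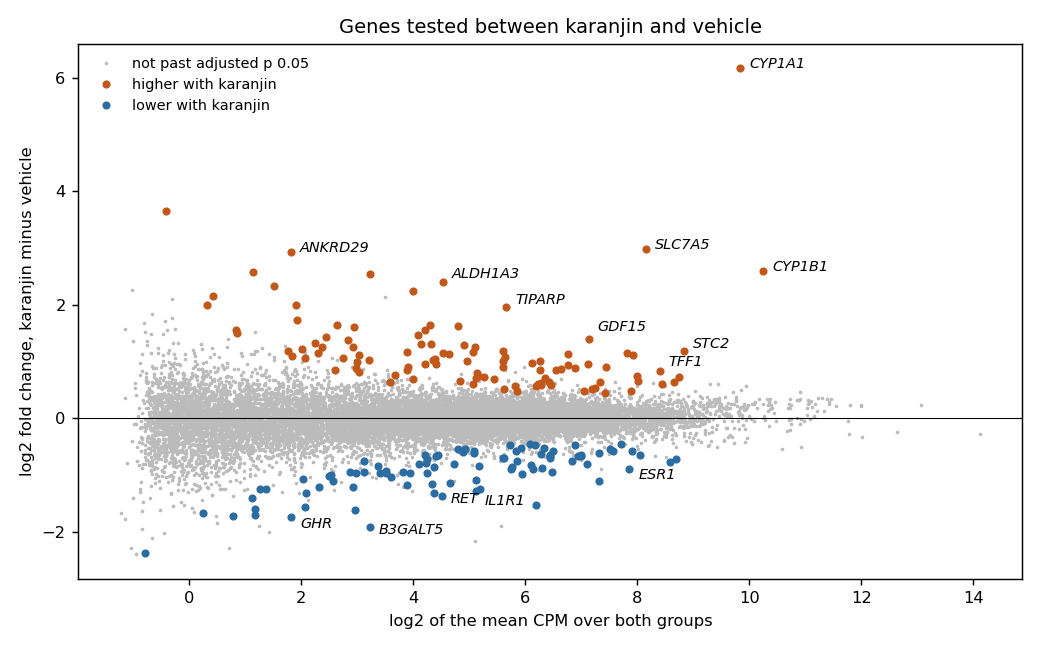
Each point is 1 of the 15068 tested genes, with the log2 of its mean CPM over both groups (n = 3 each) on the horizontal axis and its log2 fold change, karanjin minus vehicle, on the vertical axis. Orange points are the 105 higher genes and blue points the 91 lower genes at an adjusted p of 0.05; CYP1A1 sits alone at a log2 fold change of 6.17.

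By the rule for the largest changes, the other higher genes were ANKRD29, IRAG1, CREG2, ALDH1A3 and ALDH3A1. ANKRD29 rose from 0.799 ± 0.190 to 6.22 ± 0.981 CPM and CREG2, a secreted glycoprotein, from 2.75 ± 0.325 to 15.9 ± 5.45 CPM. IRAG1, a substrate of cGMP-dependent protein kinase, rose 5.96-fold from 0.638 CPM. The aldehyde dehydrogenases ALDH1A3 and ALDH3A1 rose 5.30-fold and 5.01-fold. The largest falls were those of B3GALT5, a galactosyltransferase (14.7 ± 3.89 to 3.92 ± 0.539 CPM, 3.77-fold lower), GHR, the growth hormone receptor (3.33-fold lower), and NR4A3, an orphan nuclear receptor (3.31-fold lower). The long noncoding RNAs TM4SF18-AS1 and LINC02021 were 3.28-fold and 3.07-fold lower. ADAM2, the sulfotransferase CHST1 and the axon guidance ligand SLIT1 were 3.16-fold, 3.03-fold and 2.97-fold lower. Several of these folds rest on low counts. In karanjin replicates 1, 2 and 3, ADAM2 had 10, 6 and 9 counts, CHST1 21, 9 and 19, and NR4A3 6, 14 and 16. In vehicle replicates 1, 2 and 3, ALDH3A1 had 30, 16 and 9, IRAG1 16, 9 and 11, and ANKRD29 23, 8 and 16. TM4SF18-AS1 is annotated as antisense, and its value is uncertain because the strand setting of the counting is not given in the sources used here. Calls among these genes were lost without vehicle replicate 1 for IRAG1 (edgeR adjusted p = 0.057). GHR lost its call without vehicle replicate 1 or 2 or karanjin replicate 3 (0.0947, 0.0621 and 0.0795). TM4SF18-AS1 did so without vehicle replicate 2 or 3 or karanjin replicate 3 (0.0731, 0.0653 and 0.0582). SLIT1 lost its call without vehicle replicate 1, 2 or 3 or karanjin replicate 3 (0.0522, 0.0642, 0.0536 and 0.0504). ADAM2 and CHST1 did so without any 1 library other than karanjin replicate 1 (0.089 to 0.213 and 0.0642 to 0.281), NR4A3 without any 1 of the 6 (0.0552 to 0.262). ALDH3A1 lost its call without vehicle replicate 1, 2 or 3 (0.099, 0.0709 and 0.0574).

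The test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, for which CYP1A1 had a log2 fold change of 6.17 (SE 0.169, adjusted p = 2.91e-07) and ESR1 one of −0.89 (SE 0.112, adjusted p = 0.00584). Numbers of higher and lower genes were 27 and 8 without vehicle replicate 1, 37 and 14 without vehicle replicate 2, and 54 and 17 without vehicle replicate 3. They were 188 and 166 without karanjin replicate 1, 101 and 82 without karanjin replicate 2, and 47 and 28 without karanjin replicate 3. Of the 196 genes, 33 passed in all 6 fits that left out 1 library, among them CYP1A1, CYP1B1, TIPARP, SLC7A5, STC2, GDF15, B3GALT5 and IL1R1. All 196 kept their sign in each of these fits. That is built in, because the groups of these genes did not overlap, and it adds no support.

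Genes of the AhR battery, the set of AhR-responsive enzymes, transporters and feedback regulators fixed beforehand, rose with karanjin. Of 17 tested members, 9 rose, none fell and 8 did not pass (12 higher and 1 lower adjusted over the list alone, the lower one being FAM43A). Besides CYP1A1, SLC7A5, CYP1B1, ALDH1A3 and ALDH3A1, the genes that rose were TIPARP and AHRR, which encode negative feedback regulators of AhR, STC2, a secreted glycoprotein, and ABCG2, an efflux transporter. TIPARP rose from 20.7 ± 2.08 to 80.1 ± 13.3 CPM, STC2 from 281 ± 7.995 to 636 ± 69.8 CPM, ABCG2 from 67.9 ± 6.91 to 149 ± 15.8 CPM and AHRR from 55.04 ± 3.68 to 99.1 ± 9.28 CPM. CYP1B1 went from 346 ± 25.0 to 2076 ± 419 CPM and SLC7A5 from 64.0 ± 3.62 to 507 ± 71.3 CPM. CYP1B1 and ALDH1A3 overlap annotated antisense genes that were also called higher. SLC7A5 has pseudogenes. The levels of these 3 genes are therefore uncertain.

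Some members of the AhR battery did not pass or were not tested. NQO1, a quinone reductase induced through both AhR and NRF2, was at 1945 ± 76.6 CPM in vehicle and 2336 ± 141 CPM with karanjin, a log2 difference of 0.26 that did not pass (edgeR adjusted p = 0.285). UGT1A6, chosen after its values were seen, had a log2 fold change of 0.91 (edgeR adjusted p = 0.107). UGT1A genes share exons, so its level is uncertain. Adjusted over the list alone, edgeR's p was 0.0365 for NQO1 and 0.00473 for UGT1A6, so both were among the higher members by that count. AHR itself, which encodes the receptor, was at 31.7 ± 2.70 and 25.0 ± 5.52 CPM (log2 fold change −0.34, edgeR adjusted p = 0.412). CYP1A2, the neighbour and paralog of CYP1A1, was below the expression filter and outside the rule for named genes. It had 0 of 56862751 counts in the vehicle group and 23 of 44599003 in the karanjin group (7, 6 and 10 in replicates 1, 2 and 3), at least 7.44-fold higher against a floor of 3 counts over the group with the total of vehicle replicate 1 halved, and 9.77-fold with its total as deposited. Its level is uncertain, since the handling of reads shared with CYP1A1 is not given.

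CYP1A1 (ENSG00000140465) lies on chromosome 15 of GRCh38 from 74719542 to 74725610 on the minus strand, CYP1A2 from 74748844 to 74756202 on the same chromosome, CYP1B1 on chromosome 2 from 38066973 to 38109902 on the minus strand and ESR1 on chromosome 6 from 151656691 to 152129619 on the plus strand. The counts are per gene and do not separate exons, introns or untranslated regions.

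Camera, limma's competitive list test on the edgeR data, placed the AhR battery above other genes (median log2 fold change 0.91, Benjamini-Hochberg adjusted p = 1.11e-83 over 30 lists), and the call held with an estimated correlation (adjusted p = 0.00114). Here and for each list called by camera, the value with an estimated correlation was the highest of 14 alternatives, save for the stromal list. ALDH3A1 lost its own call without vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.099, 0.0709 and 0.0574) and AHRR without vehicle replicate 1 or 2 (0.057 and 0.0513); over 14 alternatives the highest value of ALDH3A1 was 0.155.

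**Figure D2:**
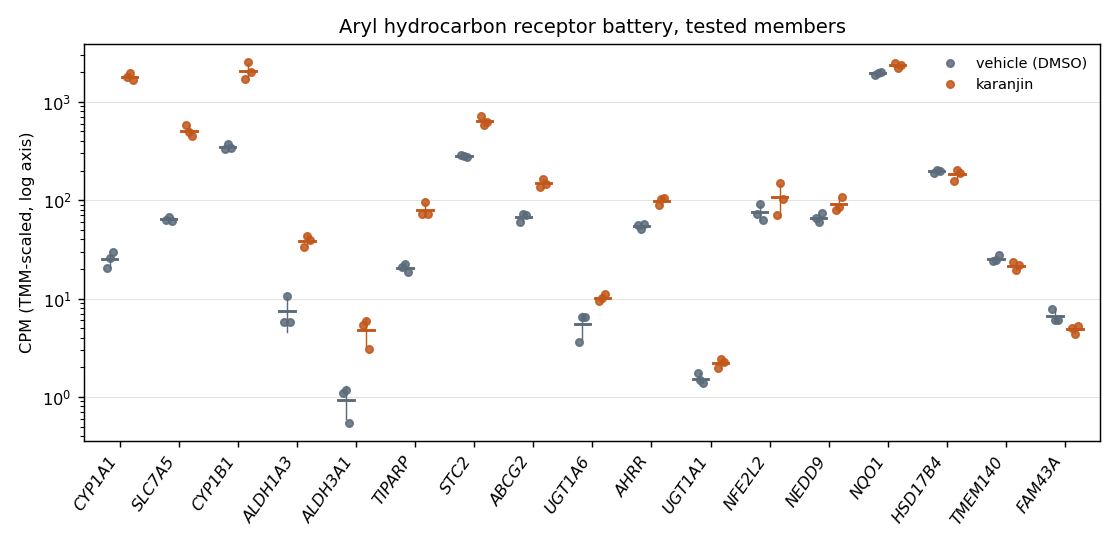
CPM on a log axis for the 17 tested members of the AhR battery, in order of log2 fold change, with vehicle in grey and karanjin in orange; each point is 1 library (n = 3 per group), horizontal bars are means and vertical lines 1 SD. CYP1A1 rose from a mean of 25.3 to 1805 CPM, whereas NQO1 lay at 1945 and 2336 CPM and did not pass when adjusted over all tested genes.

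The estrogen-related genes moved in both directions. ESR1 fell, and GPER1, a G protein-coupled estrogen receptor, fell from 20.4 ± 0.685 to 10.5 ± 1.68 CPM (1.96-fold lower). Among 37 tested genes known to be induced by estradiol in MCF-7 cells, 3 rose (AREG, STC2 and TFF1), 1 fell (RET) and 33 did not pass; adjusted over the list alone, 6 were higher and 6 lower. AREG, an epidermal growth factor receptor ligand, went from 9.08 ± 1.34 to 24.9 ± 2.58 CPM and TFF1, a secreted trefoil peptide, from 243 ± 15.1 to 432 ± 84.2 CPM, while RET, a receptor tyrosine kinase, went from 32.9 ± 3.94 to 12.7 ± 2.40 CPM. STC2 is counted in the AhR battery too.

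Estradiol-induced genes that did not pass included GREB1, a receptor cofactor (118 ± 7.21 and 160 ± 26.9 CPM, edgeR adjusted p = 0.151), PGR, the progesterone receptor (4.39 ± 1.19 and 4.35 ± 1.43 CPM, adjusted p = 0.992), and CCND1, cyclin D1 (981 ± 18.4 and 907 ± 38.4 CPM, adjusted p = 0.620). Adjusted over the list alone, edgeR's p was 0.0212 for GREB1, 0.967 for PGR and 0.364 for CCND1. GREB1 was called higher without a low-count filter and with length and GC offsets, and in no fit that left out a single library. ESR2, encoding estrogen receptor beta, was below the filter with 18, 3 and 4 counts in vehicle replicates 1, 2 and 3 and 1, 6 and 2 in the karanjin replicates. Of 19 tested genes known to be repressed by estradiol, 4 fell (IL1R1, PNPLA7, MAN1A1 and TP53INP1), 2 rose (GDF15 and BMF) and 13 did not pass, PNPLA7 and MAN1A1 being named after their values were seen; adjusted over the list alone, 8 were lower and 3 higher. IL1R1, the interleukin-1 receptor, fell 2.42-fold, GDF15, a stress-induced cytokine, rose 2.65-fold and BMF, a pro-apoptotic BCL2-family member, rose 1.91-fold.

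Camera gave no call for the estradiol-induced genes (median log2 fold change 0.02, adjusted p = 0.402, 0.220 to 0.921 over 14 alternatives). The estradiol-repressed genes were lower as a list (median log2 fold change −0.21, camera adjusted p = 0.00103). That call was lost with an estimated correlation (adjusted p = 0.184) and held with fry (adjusted p = 0.0314). IL1R1 was the 1 lower member of the list without vehicle replicate 1, 2 or 3. The list had 2 lower members without karanjin replicate 3 and 7 without karanjin replicate 1. ESR1 lost its call without vehicle replicate 1 (edgeR adjusted p = 0.059) and RET without vehicle replicate 1 or 2 (0.057 and 0.051). The same held for TFF1 without vehicle replicate 1, 2 or 3 (0.196, 0.117 and 0.148), BMF without vehicle replicate 1 (0.059), and GPER1 without vehicle replicate 1, 2 or 3 or karanjin replicate 3 (0.134, 0.0963, 0.0924 and 0.086).

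**Figure D3:**
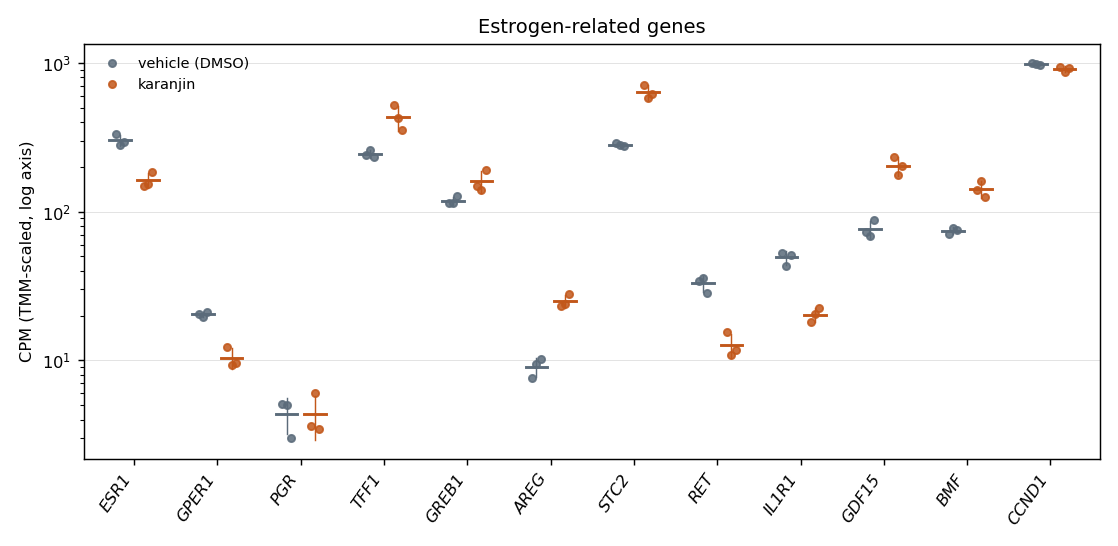
CPM on a log axis for estrogen receptor genes and estradiol-responsive genes, with vehicle in grey and karanjin in orange; each point is 1 library (n = 3 per group), horizontal bars are means and vertical lines 1 SD. ESR1 had means of 301 and 163 CPM and TFF1 243 and 432 CPM, while PGR, GREB1 and CCND1 did not pass when adjusted over all tested genes.

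Among 24 tested targets of NRF2, the transcription factor of the antioxidant response, 3 rose, none fell and 21 did not pass, with 13 higher and 0 lower adjusted over the list alone and 23 of 24 log2 fold changes above 0. TXNRD1, thioredoxin reductase, rose from 322 ± 16.2 to 535 ± 62.1 CPM, FTH1, the ferritin heavy chain, from 316 ± 30.2 to 493 ± 65.4 CPM, and AKR1C2, an aldo-keto reductase, from 121 ± 9.57 to 173 ± 15.3 CPM. FTH1 has processed pseudogenes and AKR1C2 near-identical paralogs, so both levels are uncertain. HMOX1, heme oxygenase 1, was at 6.08 ± 0.385 and 7.58 ± 0.970 CPM and did not pass (edgeR adjusted p = 0.438). SLC7A11, the cystine transporter, had the highest log2 fold change of the list at 2.14 (SE 0.444) and did not pass (edgeR adjusted p = 0.0978); it was singled out after its values were seen, and it passed without karanjin replicate 1 or 2. Members of the list that passed numbered 6 without karanjin replicate 1, 6 without karanjin replicate 2, and 0 without vehicle replicate 1, 2 or 3 or karanjin replicate 3.

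Camera called the NRF2 list (median log2 fold change 0.34, adjusted p = 5.45e-13), and the call held with an estimated correlation (adjusted p = 0.0255). TXNRD1 lost its call without vehicle replicate 1, 2 or 3 or karanjin replicate 3 (edgeR adjusted p = 0.128, 0.0875, 0.0743 and 0.0529), FTH1 without the same libraries (0.279, 0.1704, 0.137 and 0.109), and AKR1C2 also without these (0.283, 0.191, 0.137 and 0.169).

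Genes of G2/M and mitosis lay above 0 throughout but mostly did not pass one by one. Of 40 tested members, 2 rose (UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, and CENPA, the centromeric histone H3 variant), none fell and 38 did not pass; 14 were higher and 0 lower adjusted over the list alone. DESeq2 called 9 members higher and limma-voom 2, and edgeR called 9 without a low-count filter and 10 with length and GC offsets. UBE2C rose from 33.1 ± 1.22 to 53.3 ± 6.70 CPM and CENPA from 9.36 ± 0.237 to 14.5 ± 0.0378 CPM. MKI67, which encodes the proliferation marker Ki-67, was at 41.0 ± 11.2 and 57.1 ± 36.1 CPM (log2 fold change 0.48, edgeR adjusted p = 0.729). Of 42 tested genes of G1/S and DNA replication, none passed in edgeR's test (0 also adjusted over the list alone), 1 was higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0 (median log2 fold change −0.03, camera adjusted p = 0.615).

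The mitosis list had a median log2 fold change of 0.43 (camera adjusted p = 3.00e-11) and lost its call with an adjusted p = 0.184 with an estimated correlation. Its mean log2 change from the vehicle mean was −0.02 in karanjin replicate 1, 0.72 in replicate 2 and 0.44 in replicate 3. Without karanjin replicate 1, 9 members were higher, and 0 were higher without vehicle replicate 1, 2 or 3 or karanjin replicate 3. Without karanjin replicate 2 the median was 0.25 and the log2 fold change of MKI67 was −0.06. UBE2C lost its call without vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.222, 0.158 and 0.137) or karanjin replicate 3 (0.0505), and CENPA without any 1 library other than karanjin replicate 1 (0.0697 to 0.279).

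Karanjin replicate 1 stood apart from the other libraries. The first principal component of log2 CPM over 14027 genes held 47.3% of the variance and placed this library at 47.7, with the other 5 between −17.8 and 4.63. Among 6 classes of transcript length, its genes of the longest class had a median log2 change from the vehicle mean of −0.50 and those of the shortest 0.18. Ribosomal protein genes took 8.83% of its counts (Wilson 95% interval 8.81 to 8.84%), against 6.96% (6.95 to 6.97%) and 6.93% (6.91 to 6.94%) in karanjin replicates 2 and 3 and 6.36% (6.35 to 6.37%), 6.63% (6.61 to 6.64%) and 6.29% (6.28 to 6.30%) in the vehicle replicates.

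**Figure D4:**
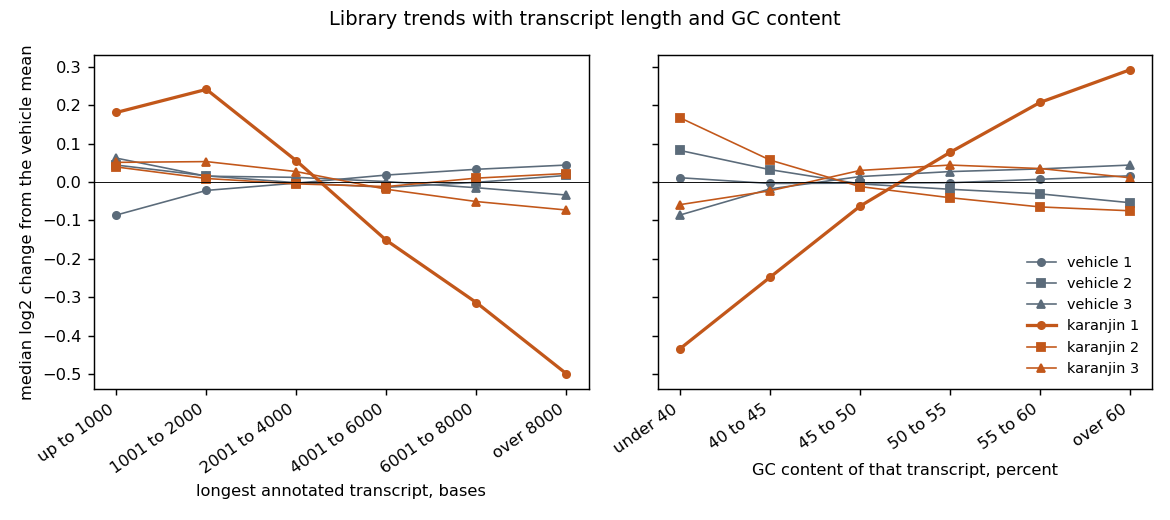
Median log2 change from the vehicle mean (vertical axis, both panels) of tested genes in classes of transcript length in bases (left) and of transcript GC percent (right), with 1 line per library. Karanjin replicate 1, the thick orange line, went from 0.18 in the class of shortest transcripts to −0.50 in that of the longest and from −0.43 under 40% GC to 0.29 over 60% GC.

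Few single genes passed in the lists of ribosome production and protein-synthesis stress. MYC rose from 50.9 ± 3.91 to 102 ± 24.7 CPM and was the 1 of 30 tested MYC and ribosome-biogenesis genes to pass (9 higher and 0 lower adjusted over the list alone), while all 30 log2 fold changes were above 0. None of 72 ribosomal protein genes passed in edgeR's test (0 also adjusted over the list alone, 0 by DESeq2 or limma-voom, and 20 higher at an unadjusted p under 0.05). Without a low-count filter 8 were called higher, and with length and GC offsets 1 was, RPL22, named after its values were seen. In the reported fit all 72 log2 fold changes were above 0; the mean log2 change was 0.55 in karanjin replicate 1, 0.13 in replicate 2 and 0.125 in replicate 3. In the list of the integrated stress response driven by ATF4, 2 of 27 rose (STC2 and SLC3A2), none fell and 25 did not pass (4 higher and 1 lower, VLDLR, adjusted over the list alone). SLC3A2, the heavy chain partner of SLC7A5, rose from 153 ± 4.89 to 333 ± 65.1 CPM. DDIT3, which encodes the stress factor CHOP, was at 8.05 ± 0.276 and 9.19 ± 1.17 CPM (edgeR adjusted p = 0.618).

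Camera called all 3 of these lists, and each call was lost with an estimated correlation. For MYC and ribosome biogenesis the median log2 fold change was 0.32 (camera adjusted p = 4.14e-10, adjusted p = 0.184 with an estimated correlation), for ribosomal proteins 0.26 (2.54e-16, adjusted p = 0.415 with an estimated correlation) and for ATF4 0.14 (1.33e-05, adjusted p = 0.338 with an estimated correlation). The mean log2 change of the ATF4 list was 0.40 in karanjin replicate 1, 0.16 in replicate 2 and 0.18 in replicate 3. Without karanjin replicate 1 the median was 0.12 for ribosomal proteins and 0.07 for ATF4, whose higher members numbered 4 with SLC7A11 and DDIT4. In the same fit MYC no longer passed (edgeR adjusted p = 0.0827). MYC also lost its call without vehicle replicate 1, 2 or 3 or karanjin replicate 3 (0.1703, 0.103, 0.137 and 0.0683), with 0.296 as the highest of 14 alternatives, and SLC3A2 without vehicle replicate 1 or 2 (0.059 and 0.0534).

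Of the markers of luminal epithelium, the cell type MCF-7 derives from, 16 of 21 had a log2 fold change below 0 and 1 passed. ESR1 fell, none rose and 20 did not pass; adjusted over the list alone, 3 were lower (ESR1, AR and CDH1) and 0 higher. AR, the androgen receptor, and the keratins given next were chosen after their values were seen. AR was at 60.1 ± 5.53 and 38.8 ± 5.97 CPM (edgeR adjusted p = 0.062). The keratins KRT8, KRT18 and KRT19 had log2 fold changes of −0.28, −0.25 and −0.27 and did not pass. Of 12 tested basal epithelial markers, CD44, an adhesion receptor, rose from 25.7 ± 1.47 to 44.4 ± 5.99 CPM, none fell and 11 did not pass (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.234).

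Camera called the luminal list (median log2 fold change −0.16, adjusted p = 2.60e-04); adjusted p = 0.268 with an estimated correlation. Its mean log2 change was −0.09 in karanjin replicate 1, −0.31 in replicate 2 and −0.17 in replicate 3. Without karanjin replicate 1, 7 members were lower (KRT8, KRT18, KRT19, SPDEF, AR, CDH1 and ESR1), and without karanjin replicate 2 the list lost its call (camera adjusted p = 0.0687). CD44 lost its call without vehicle replicate 1, 2 or 3 or karanjin replicate 3 (edgeR adjusted p = 0.124, 0.121, 0.128 and 0.0768).

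Growth-factor-induced and inflammatory genes included several that rose. Of 27 immediate early genes, 3 rose, none fell and 24 did not pass (4 higher and 1 lower, BTG2, adjusted over the list alone). The 3 were PHLDA1, from 20.2 ± 1.21 to 48.4 ± 1.81 CPM, MYC, and IER3, from 121 ± 3.17 to 226 ± 28.7 CPM. FOS and JUN, subunits of the AP-1 factor that were chosen after their values were seen, had log2 fold changes of 0.29 and 0.26 and did not pass. IER3 was also the 1 of 15 NF-kB target genes to pass (4 higher and 0 lower adjusted over the list alone). None of 17 heat shock genes passed in edgeR's test, where 4 were higher and 1, BAG3, lower both at an unadjusted p under 0.05 and adjusted over the list alone; DESeq2 called 2 higher and limma-voom 1. PARP9, an interferon-induced ADP-ribosyltransferase, fell from 26.6 ± 0.835 to 17 ± 2.21 CPM as 1 of 24 interferon-response genes, with none higher (0 higher and 1 lower adjusted over the list alone).

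Camera called each of these 4 lists, and each call was lost with an estimated correlation: immediate early (median log2 fold change 0.16, adjusted p = 9.42e-04; adjusted p = 0.343 with an estimated correlation), NF-kB (0.22, 0.0019; adjusted p = 0.184 with an estimated correlation), heat shock (0.21, 0.00105; adjusted p = 0.338 with an estimated correlation) and interferon (−0.20, 0.0275; adjusted p = 0.338 with an estimated correlation). Without karanjin replicate 1 the median was 0.07 for the immediate early list and 0.14 for the heat shock list, which then had 2 higher members and 1 lower. Means of the immediate early list were 0.32, 0.01 and 0.21 in karanjin replicates 1, 2 and 3, and those of the interferon list −0.04, −0.30 and −0.26. The interferon call was also lost without karanjin replicate 2 or 3 (camera adjusted p = 0.139 and 0.0687), and PARP9 passed in no fit without 1 library other than karanjin replicate 1 (0.0721 to 0.279). IER3 lost its call without vehicle replicate 1 or 2 (edgeR adjusted p = 0.057 and 0.0521).

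Few members of the metabolic lists passed in edgeR's test. PFKP, a phosphofructokinase, rose from 198 ± 6.73 to 277 ± 22.7 CPM as the 1 of 19 glycolysis genes to pass (2 higher and 0 lower adjusted over the list alone), and none of 44 nuclear-encoded respiratory chain genes passed in edgeR's test (0 also adjusted over the list alone, 0 by DESeq2 or limma-voom, and 5 higher at an unadjusted p under 0.05). Of 21 hypoxia genes, 2 fell, NDRG1 from 81.8 ± 9.02 to 41.4 ± 5.79 CPM and PFKFB3, a regulator of glycolytic flux, from 217 ± 6.25 to 148 ± 11.6 CPM; none rose (3 higher and 2 lower adjusted over the list alone). No member passed in edgeR's test among 24 cholesterol synthesis, 14 fatty acid synthesis and 5 metallothionein-related genes; adjusted over the list alone, 1 fatty acid synthesis gene, ME1, was higher and no gene of the other lists passed. At an unadjusted p under 0.05 there were 1 higher cholesterol gene, 1 higher and 2 lower fatty acid synthesis genes and 1 lower metallothionein-related gene; DESeq2 called 1 fatty acid synthesis gene higher, and limma-voom called 0 in these lists.

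Camera called glycolysis (median log2 fold change 0.13, adjusted p = 0.0466; adjusted p = 0.580 with an estimated correlation) and the respiratory chain (0.16, 2.94e-04; adjusted p = 0.570 with an estimated correlation), but not hypoxia (adjusted p = 0.911), cholesterol synthesis (0.291), fatty acid synthesis (0.338) or metallothioneins (0.402). The respiratory chain mean was 0.29 in karanjin replicate 1 and 0.05 and 0.06 in replicates 2 and 3, and without karanjin replicate 1 both calls were lost (camera adjusted p = 0.160 for the respiratory chain and 0.421 for glycolysis). The respiratory chain and glycolysis medians were 0.05 and 0.04 in that fit and 0.24 and 0.20 without karanjin replicate 2. Glycolysis also lost its call without vehicle replicate 1 or 2 or karanjin replicate 3 (camera adjusted p = 0.0711, 0.110 and 0.05002), and with length and GC offsets (0.161). Without vehicle replicate 1 and karanjin replicate 1 together, the value was 0.533 for glycolysis and 0.254 for the respiratory chain. PFKP and PFKFB3 passed without karanjin replicate 1 or 2 but not without any other single library (edgeR adjusted p = 0.109 to 0.283 for PFKP and 0.0644 to 0.182 for PFKFB3), and NDRG1 lost its call without vehicle replicate 1 or 3 (0.0936 and 0.0626).

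Death, p53 and drug-metabolism lists were not called by camera. Of 26 p53 targets, GDF15 rose and TP53INP1 fell, from 286 ± 17.1 to 192 ± 23.5 CPM (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.106), while CDKN1A, the cell cycle inhibitor p21, was at 519 ± 32.0 and 599 ± 100.3 CPM (edgeR adjusted p = 0.513). Of 34 apoptosis genes, BMF was the 1 to pass, by either adjustment (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.234); BCL2, the anti-apoptotic gene, was at 1.41 ± 0.508 and 1.73 ± 0.304 CPM (edgeR adjusted p = 0.784). Of 14 tested drug-metabolism and transport genes, a list that shares ABCG2 with the AhR battery, ABCG2 alone passed (3 higher and 1 lower, ABCC5, adjusted over the list alone; camera adjusted p = 0.198). FN1, fibronectin, fell from 33.6 ± 0.945 to 19.2 ± 1.73 CPM as the 1 of 15 mesenchymal and TGF-beta genes to pass (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.916).

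Without karanjin replicate 3 the p53 list passed (camera adjusted p = 0.0498; 0.020 to 0.338 over 14 alternatives), and by fry the apoptosis list did (0.0226; up to 0.441 over 14 alternatives). TP53INP1 lost its call without vehicle replicate 1, 2 or 3 or karanjin replicate 3 (edgeR adjusted p = 0.279, 0.173, 0.148 and 0.141), as did FN1 (0.115, 0.0816, 0.0727 and 0.0597).

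No single gene passed in edgeR's test among 20 endoplasmic reticulum chaperone genes (camera adjusted p = 0.844), 28 autophagy and lysosome genes (0.911) or 27 histone genes (0 also adjusted over the list alone, and 0 by DESeq2 or limma-voom). At an unadjusted p under 0.05, 1 chaperone gene was higher and 1 lower, 2 autophagy genes were lower and 4 histone genes were lower. The histone list had a median log2 fold change of −0.16 and a camera adjusted p = 0.0251 (adjusted p = 0.432 with an estimated correlation). The call was lost without vehicle replicate 1 or karanjin replicate 2 (0.149 and 0.239, with medians of −0.11 and −0.08). The list holds replication-dependent histones, whose mRNAs lack poly(A) tails, whereas poly(A) RNA was sequenced. Its levels are therefore uncertain and cannot be read as histone expression. Markers of stromal, immune and blood cells were nearly all below the filter, with 3 of 18 tested (COL1A1, COL3A1 and CDH5). They had a median log2 fold change of −0.76 (camera adjusted p = 0.011; adjusted p = 0.237 with an estimated correlation); none passed in edgeR's test, and 1 (COL3A1) was lower adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2, with 0 by limma-voom. That call was lost without karanjin replicate 2 (camera adjusted p = 0.0904) and without a low-count filter (0.791, the highest of 14 alternatives). Markers of other cell lines also had 3 of 15 members tested (PAX8, NKX3-1 and VIL1) and gave no call (camera adjusted p = 0.234), with 0 passing in edgeR's test (0 also adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom). For hypoxia, the mesenchymal list and the autophagy list the signs of median, mean and camera's direction did not all match.

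**Figure D5:**
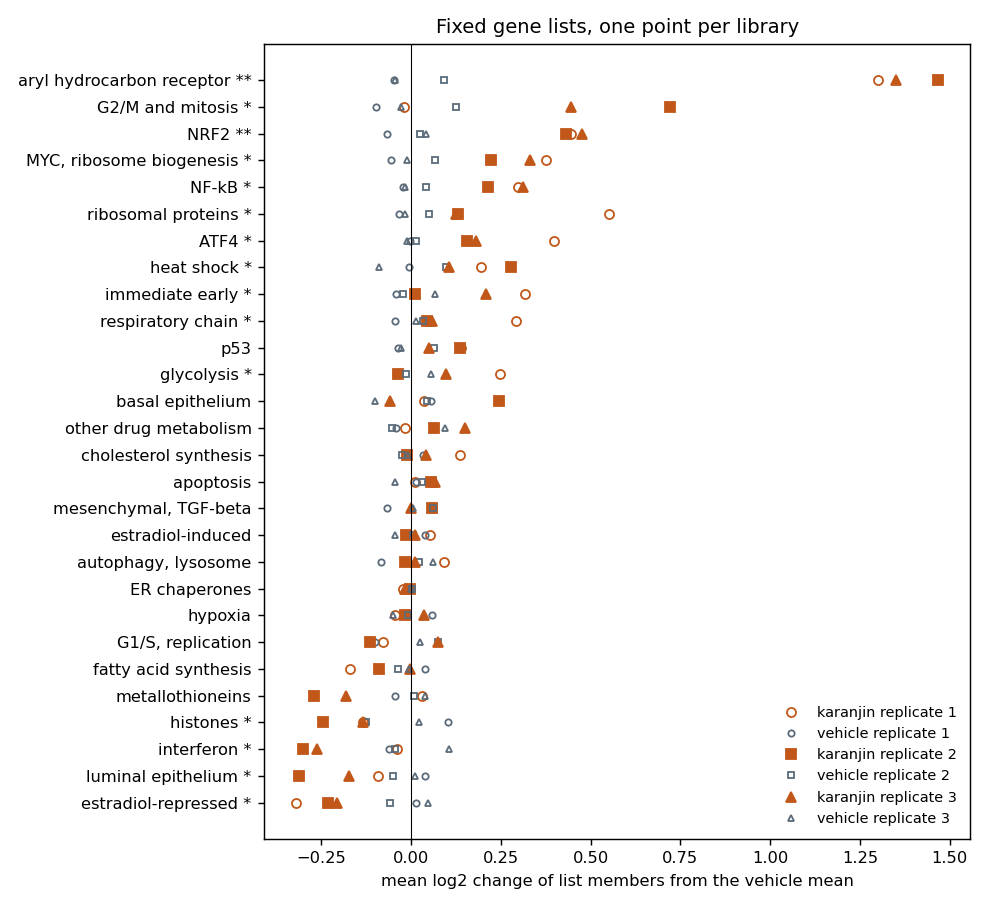
Mean log2 change from the vehicle mean of each fixed list with more than 3 tested members, with 1 point per library; karanjin libraries are orange and vehicle libraries grey, and shapes give the replicate number. One star marks a camera adjusted p under 0.05 and a second star a call that held with an estimated correlation, which only the AhR and NRF2 lists had; the AhR means were 1.30, 1.47 and 1.35 in karanjin replicates 1, 2 and 3.

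Of 30 lists tested, 16 passed by camera, 11 higher and 5 lower. Of the 30, 2 passed with an estimated correlation and 6 by fry, limma's test of whether a list's genes move on balance in 1 direction. In the simulation both missed a list of 20 genes raised 1.5-fold. A call lost with either therefore does not show that a list was unchanged. Many members are shared between lists (3 of the AhR battery, 8 of the p53 and 8 of the apoptosis lists), so the lists are not independent. All lists were fixed before the data were examined. Labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.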

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

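Alternatives chosen only after the result was seen were the halved vehicle replicate 1, the length and GC offsets, and the fit without vehicle replicate 1 and karanjin replicate 1. All 196 called genes kept their sign in every fit in which they were tested. Their groups did not overlap, so kept signs are largely built in and add no support. In each full-table alternative in which named genes were examined, 31 kept their call, CYP1A1, CYP1B1, TIPARP and SLC7A5 included. Higher and lower genes numbered 363 and 349 with no low-count filter, 209 and 194 with DESeq2, 56 and 29 at an absolute log2 fold change of at least 1, 44 and 21 at an adjusted p under 0.01, 296 and 283 with length and GC offsets, and 48 and 30 without vehicle replicate 1 and karanjin replicate 1. They ranged from 27 to 188 and from 8 to 166 when 1 library was left out. Main calls shared with the offset fit were 104 higher and 88 lower. Other scalings gave 95 to 105 higher and 81 to 102 lower genes and median log2 fold changes between −0.03 and 0.02. Same-numbered libraries had correlations of deviations of −0.015, 0.352 and 0.110, and 2 of 3 karanjin libraries correlated best with their own number. Vehicle replicate 3 and karanjin replicate 1, whose GC trends share a sign, also correlated (0.268). These values therefore cannot tell whether the numbers pair the libraries. The replicate block gave 73 higher and 52 lower genes. Of the list calls it ended that of glycolysis (camera adjusted p = 0.0563). With an estimated correlation, the estradiol-repressed and the G2/M lists had adjusted p = 0.184 each. With fry the estradiol-repressed list passed (adjusted p = 0.0314) and the G2/M list did not (0.0713). Of the lists other than the AhR, estradiol and G2/M lists, camera called 13 with the preset correlation and 1 with an estimated one (NRF2), and fry called 4 (NRF2, NF-kB, apoptosis and MYC). The camera direction turned, with no call, for endoplasmic reticulum chaperones without a filter (0.992), G1/S without vehicle replicate 2 or karanjin replicate 2 (0.907 and 0.708; 0.198 to 0.907 over all fits without 1 library), hypoxia without vehicle replicate 1 or karanjin replicate 1 (0.791 and 0.974; 0.651 to 0.974), with offsets (0.867) and without both (0.660), the mesenchymal list without a filter (0.912), with offsets (0.829) and without vehicle replicate 2 or karanjin replicate 3 (0.907 and 0.963; 0.636 to 0.975, and 0.597 without both of the libraries named first), and autophagy without a filter (0.9002) and in 4 fits without 1 library (0.708 to 0.975; 0.366 to 0.975 over all 6). The log2 fold change of PGR turned to 0.005 without a filter, 0.003 with DESeq2, 0.014 with halved counts, 0.206 with offsets, 0.262 without both libraries and 0.097 to 0.152 in 4 fits without 1 library (−0.308 to 0.152 over all 6), and that of MKI67 to −0.064 without karanjin replicate 2 (−0.064 to 0.891). For each of these the cause was not tested; fits without a library have fewer samples by construction. Of 44 named calls, 28 were lost without vehicle replicate 1, 25 without vehicle replicate 2, 21 without vehicle replicate 3, 2, 5 and 19 without karanjin replicates 1, 2 and 3, 21 without vehicle replicate 1 and karanjin replicate 1, and 13 with the replicate block (NR4A3, ADAM2, CHST1, FTH1, AKR1C2, TP53INP1, UBE2C, CENPA, PFKFB3, PFKP, PARP9, MYC and CD44, adjusted p from 0.0646 to 0.112). Depth limits low genes: 3 counts in vehicle replicate 2 equal 0.225 CPM.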

Other observations

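All tests of hypotheses below were chosen only after the result was seen, except those of other sample splits, of transcript length, of GC content and of non-overlapping neighbours; the genes outside the naming rule were also picked after their values were seen.

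Several called genes fall outside the lists and the rule for named genes. Transcription factor genes that rose included RUNX2 (log2 fold change 1.31, SE 0.14), FOSL2 (0.89, SE 0.09), CEBPD (0.85, SE 0.16), PPARG (0.73, SE 0.11) and TFAP2A (0.71, SE 0.11). Other transcription factor genes fell, among them ESR1 and NR4A3 given above, and the class was not tallied or tested. STRA6, a membrane receptor for retinol-binding protein, rose by a log2 fold change of 1.03, and LAMA3, a laminin chain, by 1.63. ARNT2, a paralog of the AhR partner ARNT, had a log2 fold change of −0.90 (SE 0.15), and CRY2, a repressor of the circadian clock, −0.88 (SE 0.10). Secreted factors that fell included TGFB2 (−0.96), DKK1 (−0.82), IGFBP5 (−1.09) and SLIT2 (−1.22), the last a paralog of SLIT1. Other secreted factors rose, among them STC2, GDF15, AREG and TFF1 given above, and this class was not tallied or tested either. RUNX2, FOSL2 and STRA6 overlap other called genes, so their levels are uncertain. All of these genes passed edgeR's adjusted p of 0.05 with all 3 karanjin values on 1 side of the vehicle values. Among the genes given with values in this paragraph, RUNX2 and FOSL2 passed in every fit that left out 1 library, and the others did not.

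Genes that rose lay near one another more than random sets of genes did. Within 100 kb, 15 pairs of higher genes did not overlap on the genome, against a median of 1 and a 95th percentile of 4 in 10000 random sets of tested genes matched on expression (permutation p = 1e-04, the smallest they can give), and without the ALDH1A3 locus 8 pairs remained (permutation p = 2e-04); the 91 lower genes gave 4 pairs (permutation p = 0.0251). At the ALDH1A3 locus on chromosome 15, ALDH1A3 rose together with 4 annotated neighbours (GCAWKR, ALDH1A3-AS1, AC015712.1 and LRRK1), and EDC3 rose 23.2 kb from CYP1A1 (log2 fold change 0.95, SE 0.09). Another 7 pairs overlap, among them CYP1B1 with CYP1B1-AS1, and since the strand setting is not given their reads cannot be told apart. Transcription past the end of a gene may link the non-overlapping pairs and cannot be told apart from shared regulation, because only 1 of the 15, ANKRD29 with LAMA3, is divergent so that neither gene lies downstream of the other. A shared rise of neighbouring genes is a hypothesis that these counts leave open, with no chromatin data used here.

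Vehicle replicate 1 had 27128751 counts, 2.03 times the total of vehicle replicate 2. Its genes with a count of exactly 2 outnumbered those with a count of 1 by a ratio of 2.23, against 0.478 to 0.528 in the other 5 libraries, and 57.9% of its counts above 0 were even, against 45.1 to 45.7%. Deeper sequencing would bring more detected genes, but thinned to the total of vehicle replicate 2 the library had 22204 genes with a count, 93.8% of the 23663 there, which argues against it. A candidate explanation is that both reads of a pair were counted singly in this library; the counting settings are not given, and no biological explanation was tested. Halving its counts left 102 higher and 80 lower genes, of which 101 and 80 were among the calls reported.

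Karanjin replicate 1 lay apart from the other libraries, with r of at most 0.983 with any other library, against 0.989 between karanjin replicates 2 and 3 and 0.991 to 0.992 among vehicle libraries. Its deviation from the other karanjin libraries had a Spearman correlation across genes of −0.389 with transcript length and 0.602 with GC percent (genes are not independent replicates), and that of karanjin replicate 2, measured against a pair that includes replicate 1, had 0.313 and −0.580. Both trends may come from a technical difference such as RNA quality or amplification, though they overlap and cannot be separated here. Removing them lowered the SD of the deviation from 0.487 to 0.369, and in karanjin replicate 2 from 0.418 to 0.329. The trends were fitted to the same counts, so such a fall is largely built in and adds no support. The AhR list argues against a weaker or stronger AhR response: its mean log2 change was 1.30 in this library, and 1.35 and 1.47 in karanjin replicates 3 and 2. Its low mitosis and high ribosomal protein means remain open as biology or bias.

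Regrouping the 6 libraries 3 against 3 gives 10 splits, too few for a share under 0.05. The real split gave 196 genes and was the 1 split to give that many, and the highest of the others gave 0. Each of the others placed karanjin and vehicle libraries together in both groups. A real effect then widens the spread within groups, so few calls there are largely built in.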
